A study of Homo sapiens with 6 samples.

How the data were processed

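RNA sequencing libraries from SW872-S liposarcoma cells, 3 of NC and 3 of TP53INP2_OE, were analysed from 1 deposited table of gene expression. Per the labels' protocols, cells were grown in DMEM with fetal bovine serum, RNA was taken up in Trizol, and libraries were made with the Illumina TruSeq RNA kit. Groups and replicate numbers were taken from the sample titles. The design text mentions 2 cell sources, which were taken to be the 2 groups of the one line; it does not say more. The authors deposited FPKM values (fragments per kilobase of gene, scaled by a total set for each library) for 60843 genes. Gene name, position, length and type were given too, per the file headers. The submitters' processing notes name Bowtie 0.12.2 and the builds mm8 and GRCh38, with no statement of what each was used for, and the step that assigned reads to genes is not given in the sources used here. The gene positions were compared with GENCODE release 29 on GRCh38. Of the gene IDs, 96.2% were found there, 99.92% of these on the same chromosome and 92.7% with the same start or the same end, so positions are given as the table holds them, on GRCh38.

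FPKM times gene length, divided by the smallest such value above 0 in a library, gave whole numbers for 100% of values above 0 in each library, within a tolerance of 0.01. These were taken as the reads behind each value. They summed to between 16038062 and 17607612 reads per library, and to between 98.8% and 100.1% of the total the authors scaled by. They serve to show depth, and a gene with few reads has a value that moves in coarse steps. Whether reads were assigned by strand is not given in the sources used here, so overlapping and antisense genes cannot be separated with certainty. No 2 libraries were the same within sampling noise. The chi-square per degree of freedom over genes with at least 10 reads ranged from 2.48 to 4.6 within groups and from 12.2 to 29.2 between them.

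The test, the gene lists and the rule for naming genes were fixed before the data were examined. Values were taken as log2(FPKM + 1), genes with a mean of at least 0.5 FPKM over the 6 libraries were kept (14791, of which 11278 are protein-coding), and groups were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with trend, Benjamini-Hochberg adjustment, threshold 0.05). Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Adjusted p-values for genes come from this limma fit unless another setting is named beside them. The plan held a count-based test for the case that the table held raw counts. It was not used, since the table holds FPKM, and limma's voom on the recovered reads was run as an alternative.

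There were 26 gene lists, of which 24 with at least 5 tested members entered limma's camera (preset correlation 0.01, Benjamini-Hochberg over the lists). Camera with an estimated correlation and limma's fry were run beside it. With the estimated correlation no list passed the adjusted threshold, and 1 list had an unadjusted p below 0.05. The nuclear-encoded oxidative phosphorylation list lost its call although its estimated correlation, 0.00836, was below the preset 0.01. For that list a larger correlation between genes is therefore not the reason. In this mode camera takes its degrees of freedom from the 6 libraries, and with a preset correlation from the genes. A call lost there is no sign of correlated genes by itself. Counts of members are adjusted over all tested genes and, separately, adjusted over the list alone. List symbols were matched to older names where the table holds those, as for RIGI, held as DDX58.

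The rule for naming genes takes TP53INP2, YAP1, WWTR1, CCN1, CCN2, ANKRD1, PPARG and CEBPA whatever their result. It adds the 10 largest increases and the 10 largest decreases among genes past the threshold that have at least 1 FPKM in the higher group, libraries of the 2 groups fully apart and a standard symbol. From each list it takes up to 4 members past the threshold with the largest change, or 2 of the highest expressed members where fewer than 2 pass. Some genes are not reported here by name, and the counts of their lists include them. Genes named outside this rule were chosen after their values were seen: IFIT3, OASL, IFIH1, CXCL10, CXCL11, IFNB1 and the other interferon-stimulated genes that did not pass, MT-CO3, MT-ND3, PINK1, TAX1BP1, ATG9A, PTPRC, PI16 and those of the closing section's opening paragraphs.

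GC content of the longest GENCODE 29 transcript was known for 98.4% of tested genes and 99.2% of those past the threshold. For the GC and length correction, chosen after seeing the data, each library's deviation from the gene mean was fitted with natural splines (5 degrees of freedom each) on GC content and log2 gene length, and the fitted trend was subtracted before the same limma test. A change tied to GC content by biology is removed by it together with any technical one. Alternatives fixed in advance covered the pseudocount, the filter, the scaling, a replicate block, robust hyperparameters, each library left out, a minimum fold, the list test and lists without their most changed member. Voom, the GC corrections and protein-coding genes alone were added after seeing the data.

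The functions were tested on simulated data with the real genes and depths and no GC trend. For TP53INP2_OE against NC, 83% of genes changed by 1 and 20% of genes changed by 0.5 on the log2 scale were recovered among 14791 genes, with 9 false calls. With a simulated GC trend of 0.3 per 10 points of GC between the groups, 3677 unchanged genes passed before the correction and 10 after it, on 14548 genes. The simulated trend was linear and the same in all TP53INP2_OE libraries, with a fixed dispersion and no trend with length. The real slopes differed between libraries of a group, so the real data may hold more false calls. Figures were drawn with matplotlib in Python.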

Results

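Gene expression was measured by RNA sequencing in SW872-S, a human liposarcoma cell line, in 2 groups of 3 libraries. One group carried a plasmid that overexpresses TP53INP2 and is called TP53INP2_OE, and the other was the negative control, called NC. The design text speaks of 2 cell sources without saying what these are, while the labels name SW872-S for all 6 libraries, so a further difference in source between the groups is not excluded. TP53INP2 encodes a protein that moves between nucleus and cytoplasm and takes part in the formation of autophagosomes. The comparison addresses how a raised TP53INP2 level changes the transcriptome of liposarcoma cells, in a study concerned with mitophagy and with YAP, the transcriptional coactivator of the Hippo pathway. The deposited table held FPKM values for 60843 genes, of which 32504 were above 0 in at least 1 library. The values corresponded to between 16038062 and 17607612 reads assigned to genes per library. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

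TP53INP2 (chromosome 20, positions 34704339 to 34713439, a protein-coding gene) rose from 9.92 ± 0.64 FPKM in NC to 23.1 ± 4.09 FPKM in TP53INP2_OE (SD, n = 3 each), a ratio of 2.33. All 3 TP53INP2_OE libraries lay above all 3 NC libraries. The log2 fold change was 1.13 with a standard error of 0.12 (limma, adjusted p = 0.00282). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest value that 3 against 3 libraries can give. Reads from the plasmid and from the chromosomal gene are summed in these values.

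YAP1 RNA was at 31.3 ± 1.31 FPKM in NC and 34.1 ± 0.57 FPKM in TP53INP2_OE, a difference that did not pass the threshold (log2 fold change 0.12, adjusted p = 0.0568). YAP1 passed without NC replicate 3 (0.0380), among genes of at least 5 FPKM (0.0393), among protein-coding genes (0.0454), with TPM (0.0482), with quantile normalization (0.0226) and with voom (0.0305), while after GC and length correction its log2 fold change was -0.0047 (adjusted p = 0.955). WWTR1, which encodes the YAP paralog TAZ, had a log2 fold change of 0.057 (adjusted p = 0.360), which turned to -0.13 after that correction (adjusted p = 0.0665). Among 20 tested YAP/TAZ target genes, 5 rose and 5 fell, or 6 and 6 adjusted over the list alone, and the list did not stand apart from other genes (camera adjusted p = 0.757). NT5E, the cell surface enzyme CD73, rose from 89.0 ± 3.85 to 137 ± 4.96 FPKM (log2 fold change 0.61, adjusted p = 0.00166), and F3, which encodes tissue factor, rose by 0.28. CCN1, a secreted matricellular protein, fell by 0.25 (162 ± 4.73 to 136 ± 6.91 FPKM, adjusted p = 0.00748), and FJX1 fell by 0.52. The targets CCN2 (log2 fold change -0.0605, adjusted p = 0.207) and ANKRD1 (0.16, adjusted p = 0.0687) did not pass, although ANKRD1 passed without TP53INP2_OE replicate 1 (0.0396), among genes of at least 5 FPKM (0.0375), among protein-coding genes (0.0390) and with quantile normalization (0.0421). Of 23 Hippo pathway components, 7 rose and 4 fell, or 9 and 5 adjusted over the list alone (camera adjusted p = 0.455). TAOK1, a kinase upstream of the pathway, and MOB1B rose by 0.33 and 0.36, while TEAD2, a DNA-binding partner of YAP, and TAOK2 fell by 0.45 and 0.37. After the correction for GC content and gene length described with the genome-wide counts, 2 YAP/TAZ targets rose and 3 fell, and 0 Hippo components rose and 2 fell. F3 (0.18), TAOK1 (0.12), MOB1B (0.12) and TAOK2 (-0.11) no longer passed, and FJX1, TEAD2, CCN2 and ANKRD1 had corrected log2 fold changes of -0.22, -0.24, 0.0019 and 0.051. These are RNA levels, and YAP protein was not analysed here.

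**Figure D1:**
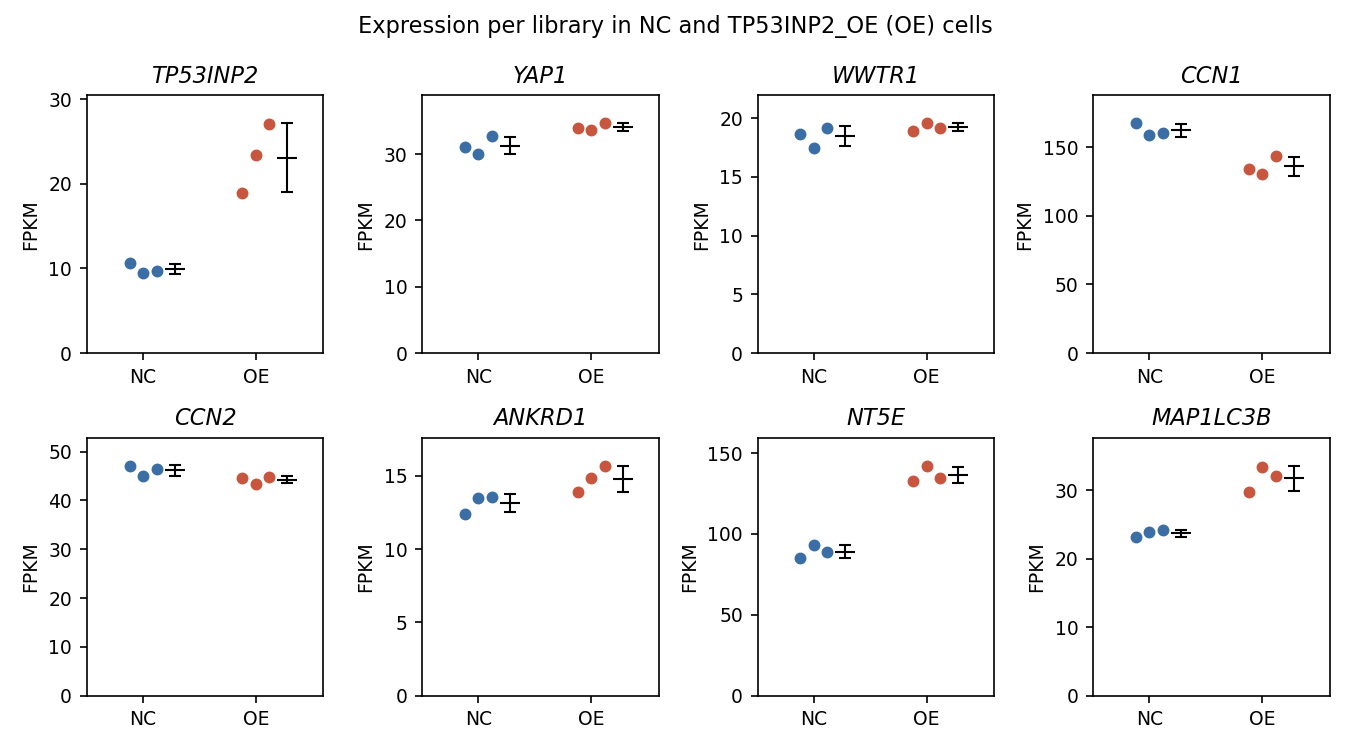
FPKM of 8 genes in each library of NC and TP53INP2_OE (OE); points are libraries, and the black bar beside them is the mean with its SD (n = 3 per group). TP53INP2, NT5E and MAP1LC3B lay higher in all 3 TP53INP2_OE libraries and CCN1 lower, and they passed the adjusted threshold. YAP1 and ANKRD1 also lay higher in all 3 and CCN2 lower, but did not pass, and neither did WWTR1, whose libraries overlapped.

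Across the transcriptome, 2430 genes rose and 2753 fell among the 14791 tested (5183 in all, adjusted p below 0.05), with a median absolute log2 fold change of 0.30. Of these, 37 that rose and 30 that fell changed by 1 or more on the log2 scale. The 3 libraries of one group lay entirely above those of the other for 7507 genes, 50.8% of those tested, where chance gives 10%. The largest increases by the naming rule included IFI44 (37.2 ± 4.09 to 96.1 ± 2.61 FPKM), DDX60 (7.93 ± 0.88 to 20.7 ± 0.23) and DDX58 (22.8 ± 2.72 to 54.2 ± 2.42), which take part in antiviral responses. FGF2, a fibroblast growth factor, rose from 5.74 ± 0.62 to 14.5 ± 0.88 FPKM, SPOCK1, an extracellular matrix proteoglycan, from 15.4 ± 1.86 to 35.1 ± 3.03, and RSAD2, an antiviral enzyme at 9.24 ± 0.95 FPKM in NC, rose by 1.17 on the log2 scale. LTB, which encodes lymphotoxin beta, fell from 8.23 ± 0.45 to 2.02 ± 0.28 FPKM. MRPL12, a mitochondrial ribosomal protein, fell by 1.43, PSENEN, a gamma-secretase subunit, by 1.13 and FAM207A by 1.10 on the log2 scale. The other genes named by the rule are short or rest on few reads. SNORD101 had between 5 and 18 reads per library, and TRBJ2-3, TRBJ2-4 and SNORD65C had at most 13. RNA5SP219 had no read in NC and 1 to 4 reads in TP53INP2_OE, so no fold is given. SPCS2P4 (log2 fold change 1.37) is a pseudogene whose reads may be shared with its parent gene, so its value is uncertain. FAM27B fell by 1.49, and the mitochondrial transfer RNA genes MT-TH and MT-TY fell by 1.45 and 1.06, with fewer than 100 reads per library in each of these 3.

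The fold changes followed the GC content of the transcripts. Across 11270 protein-coding genes with a known GC content, Spearman's rho between log2 fold change and GC content was -0.783, with genes as the units, which are not independent replicates. When these genes were divided into 10 groups of similar size by GC content, 688 rose and 4 fell in the group with the lowest GC content (median 36.9%), and 2 rose and 739 fell in the group with the highest (median 64.2%). Each library's deviation from the gene mean was fitted on GC content and gene length. Its slope per 10 points of GC was 0.124, 0.109 and 0.081 in the NC libraries and -0.073, -0.155 and -0.086 in the TP53INP2_OE libraries. These slopes are relative to the mean of the 6 libraries, so opposite signs follow once the 2 groups differ. When GC content and gene length were fitted out of each library, a step chosen after seeing the data, 581 genes rose and 1004 fell among 14548. That correction kept 455 of the 2395 genes that had risen and 850 of the 2745 that had fallen, and the share of higher calls went from 46.9% to 36.7%. Without NC replicate 1 the uncorrected count was 3276, with 1460 higher and 1816 lower, and without NC replicate 2 the number higher was 1614. TP53INP2, IFI44, DDX60, DDX58, FGF2, SPOCK1, RSAD2, LTB, MRPL12, PSENEN and FAM207A passed the threshold after the correction too, while SNORD101 (0.76), TRBJ2-3 (-1.49), TRBJ2-4 (-0.97) and SNORD65C (-1.90) did not. Of the 112 genes that the naming rule took and that had passed, 68 passed in the same direction after the correction, and their median absolute log2 fold change went from 0.466 to 0.282.

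**Figure D2:**
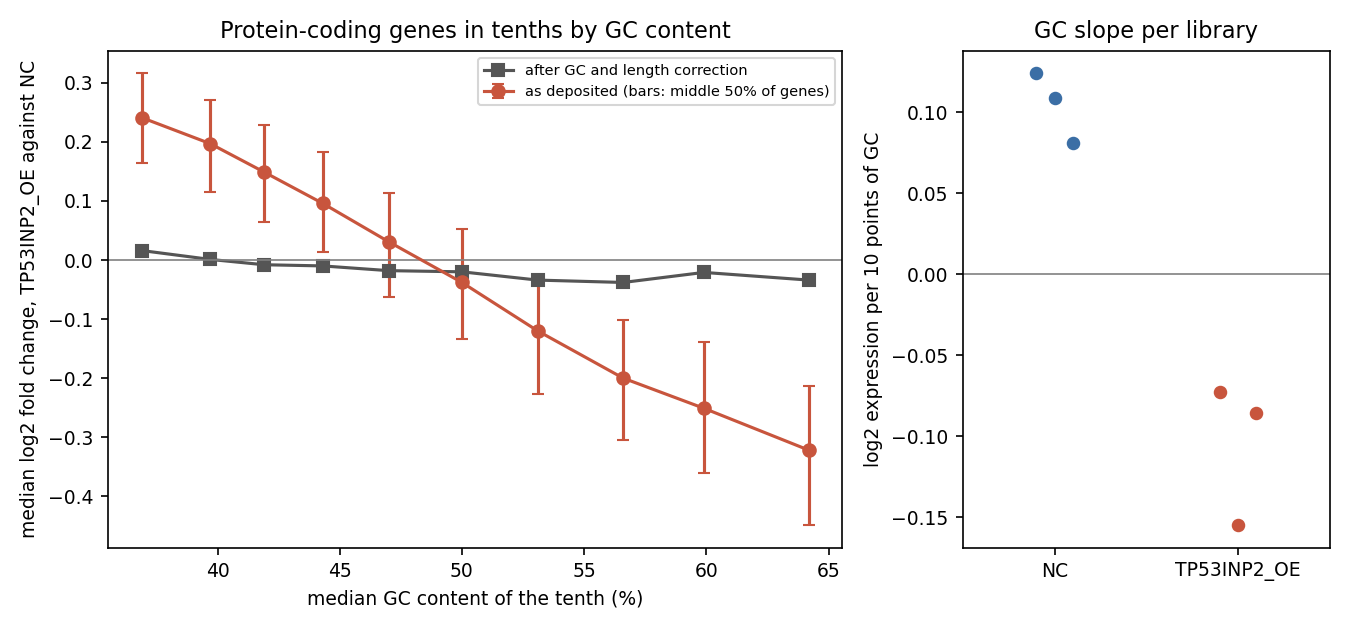
Left, the median log2 fold change (TP53INP2_OE against NC) of protein-coding genes in 10 groups by GC content in percent. Medians are shown as deposited, with bars for the middle 50% of genes, and after GC and length correction. Right, the slope per 10 points of GC of each library's log2 deviation from the gene mean, which is relative to the mean of all libraries. The medians run from 0.241 in the group of lowest GC content to -0.322 in the highest, and the slopes are above 0 in the 3 NC libraries and below 0 in the 3 TP53INP2_OE libraries.

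Of 22 interferon-stimulated genes tested, 14 rose and none fell, or 15 adjusted over the list alone, with a median log2 fold change of 0.36 (camera adjusted p = 2.23e-07; adjusted p = 0.434 with an estimated correlation). IFIT3, which binds viral RNA complexes, rose from 85.4 ± 4.78 to 171 ± 2.74 FPKM. OASL rose from 54.3 ± 2.89 to 105 ± 3.34 FPKM, and CMPK2, a mitochondrial nucleotide kinase, from 5.55 ± 0.45 to 12.1 ± 1.24. The RNA sensor gene DDX58, which encodes RIG-I, had a log2 fold change of 1.22 with a standard error of 0.08, and IFIH1, which encodes the sensor MDA5, one of 0.56. The chemokine genes CXCL10 and CXCL11 rose by 0.29 and 0.51. IFNB1, which encodes interferon beta, was at 2.13 ± 0.53 and 2.33 ± 0.48 FPKM and did not pass (adjusted p = 0.699), and neither did OAS3, IFI6, IFI27, XAF1, USP18, OAS1 and IRF7. With GC content and length fitted out, 11 members rose and the median was 0.34. CXCL10 and CXCL11 were among those that no longer passed, with log2 fold changes of 0.093 and 0.30. Of the members that had not passed, IFNB1 (-0.048) and XAF1 (-0.061) turned below 0 and IFI6 (0.16) and IRF7 (0.10) above it, with OAS3 at 0.11.

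**Figure D3:**
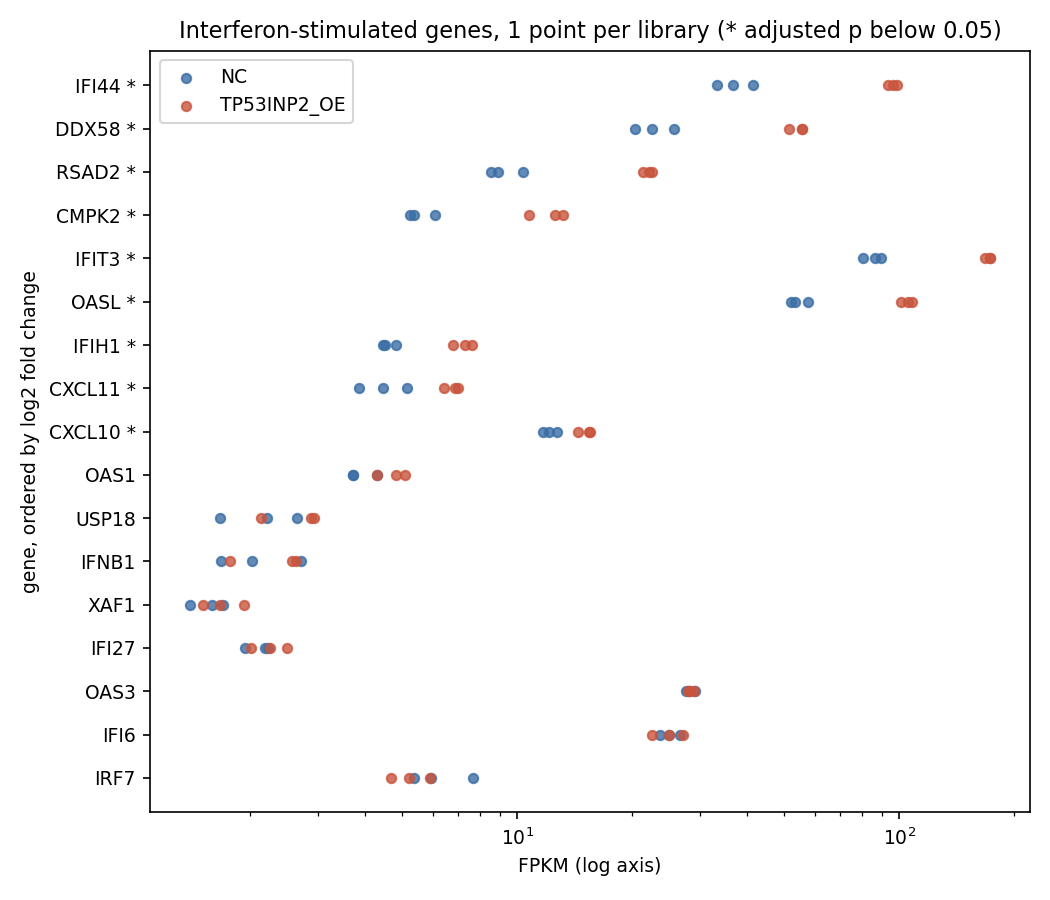
FPKM (log axis) of 17 of the 22 tested interferon-stimulated genes, ordered by log2 fold change, with 1 point per library in NC and TP53INP2_OE; an asterisk marks an adjusted p below 0.05. For IFI44, DDX58, RSAD2, CMPK2, IFIT3 and OASL the TP53INP2_OE libraries lie well to the right of the NC libraries, while OAS3, IFI6 and IFNB1 overlap.

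Of 13 protein genes of the mitochondrial genome, 10 rose and none fell, or 11 adjusted over the list alone (median 0.30, camera adjusted p = 0.00136; adjusted p = 0.697 with an estimated correlation). MT-ND4 rose from 3432 ± 23.2 to 4746 ± 362 FPKM and MT-CO2 from 4360 ± 139 to 5724 ± 490, while MT-CO3 and MT-ND3 did not pass (log2 fold changes -0.044 and -0.21). The mitochondrial chromosome took 2.88 ± 0.08% of assigned reads in NC and 3.58 ± 0.19% in TP53INP2_OE (SD, n = 3 each). Of 32 nuclear-encoded genes of oxidative phosphorylation, 11 fell and none rose, the same counts adjusted over the list alone (median -0.10, camera adjusted p = 0.0419; adjusted p = 0.615 with an estimated correlation). COX5B, a subunit of complex IV, fell from 45.0 ± 5.01 to 26.8 ± 3.70 FPKM, and NDUFA2, CYC1 and NDUFV1 fell by 0.64, 0.52 and 0.47 on the log2 scale. After the GC and length correction 7 mitochondrial genome genes rose and 10 nuclear-encoded genes fell, with medians of 0.20 and -0.15. The corrected log2 fold changes were -0.62 for COX5B, -0.55 for NDUFA2, -0.22 for CYC1 and -0.25 for NDUFV1, and -0.079 and -0.40 for MT-CO3 and MT-ND3, which did not pass. Both calls were lost under quantile normalization (adjusted p = 0.250 for each), where MT-CO2 had a log2 fold change of 0. That method gives genes of equal rank the same value in every library, so it can remove a rise among the highest genes. The nuclear-encoded call was also lost without NC replicate 3 (0.103), without TP53INP2_OE replicate 3 (0.132), without its most changed member (0.0549), with FPKM rescaled to TPM (0.0640), with voom on the recovered reads (0.0737), among protein-coding genes (0.0952) and among genes of at least 5 FPKM (0.190).

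Mitophagy and mitochondrial dynamics genes moved in both directions, with 8 rising and 8 falling of 25, or 12 and 8 adjusted over the list alone (camera adjusted p = 0.549). FIS1, a mitochondrial fission adaptor, fell from 27.7 ± 2.14 to 15.8 ± 1.91 FPKM (log2 fold change -0.77, adjusted p = 0.00301). FKBP8, a mitophagy receptor, fell from 62.4 ± 5.33 to 39.3 ± 3.65 FPKM, and TOMM7 and PGAM5 fell by 0.64 and 0.44 on the log2 scale. PINK1, the kinase that marks damaged mitochondria, fell from 10.8 ± 0.76 to 7.83 ± 1.33 FPKM, while the receptor gene TAX1BP1 rose by 0.36. After GC and length correction 1 of these genes rose and 5 fell, and PINK1 no longer passed (adjusted p = 0.0754), with a log2 fold change of -0.36 and a standard error of 0.10 against -0.43 and 0.11 before. The corrected log2 fold changes were -0.57 for FIS1, -0.33 for FKBP8, -0.72 for TOMM7 and -0.31 for PGAM5. Coding length was not fitted out. Among all tested genes with coding parts of at most 555 bases, 192 fell and 37 rose after this correction. Of 36 autophagy genes, 9 rose and 4 fell, or 10 and 6 adjusted over the list alone (camera adjusted p = 0.549). MAP1LC3B, which encodes the autophagosome protein LC3B, rose from 23.7 ± 0.50 to 31.7 ± 1.87 FPKM (log2 fold change 0.40, adjusted p = 0.00308), and ATG5 rose by 0.36. ATG4D and ATG101 fell by 0.51 and 0.43. After GC and length correction MAP1LC3B and ATG9A rose by 0.43 and 0.21 and no autophagy gene fell, with ATG5 at 0.16, ATG4D at -0.20 and ATG101 at -0.19. Lysosomal genes divided in the same manner, with 10 rising and 4 falling of 27 in both adjustments (camera adjusted p = 0.290). ATP6V1H, a proton pump subunit, and NPC1, a cholesterol transporter, rose by 0.42 and 0.32, and the cathepsins CTSD and CTSZ fell by 0.61 and 0.40. With GC content and length fitted out, 7 lysosomal genes rose and 3 fell, with CTSD at -0.31 and CTSZ at -0.18, and the list passed (camera adjusted p = 0.00235; adjusted p = 0.616 with an estimated correlation).

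Of 28 DNA replication genes tested, 13 fell and 1 rose, or 14 and 1 adjusted over the list alone, with a median log2 fold change of -0.12 (camera adjusted p = 0.0180; adjusted p = 0.697 with an estimated correlation). MCM5, a subunit of the replicative helicase, fell from 21.9 ± 0.90 to 14.7 ± 0.81 FPKM, TYMS, which makes thymidylate, from 25.9 ± 1.16 to 18.0 ± 1.25, and TK1 and the transcription factor E2F1 fell by 0.51 and 0.50 on the log2 scale. After GC and length correction 9 members fell and none rose, and the log2 fold changes were -0.37 for MCM5, -0.47 for TYMS, -0.22 for TK1 and -0.22 for E2F1. The call was lost under quantile normalization (0.147), among genes of at least 5 FPKM (0.106) and among protein-coding genes (0.0555). Of 25 G2/M genes, 7 rose and 7 fell in both adjustments (camera adjusted p = 0.808). The mitotic genes AURKB, CDC20 and BIRC5 fell by 0.40, 0.38 and 0.36, and TTK rose by 0.36. With GC content and length fitted out, CDC20 (-0.17) no longer passed, 1 gene rose, TTK at 0.18, and 5 fell, among them AURKB at -0.24 and BIRC5 at -0.29, and the list passed downward (camera adjusted p = 0.00191; adjusted p = 0.808 with an estimated correlation). Of 22 p53 targets, 4 rose and 6 fell, or 4 and 7 adjusted over the list alone (camera adjusted p = 0.735). BAX, a pore-forming death effector, fell from 28.8 ± 2.46 to 19.9 ± 0.61 FPKM, PHLDA3 and GDF15 fell by 0.68 and 0.37, and the death receptor gene FAS rose by 0.48. Cell death receptors and caspases had 8 rising and 7 falling of 24 in both adjustments (camera adjusted p = 0.912). PMAIP1, which encodes the death-promoting protein NOXA, rose from 86.1 ± 6.31 to 171 ± 10.9 FPKM (log2 fold change 0.98), and TRAF2 fell by 0.47. After the correction p53 targets had 1 rise and 1 fall, and death genes 3 and 2. PHLDA3 (-0.45) and GDF15 (-0.080) no longer passed, and BAX, FAS, TRAF2 and PMAIP1 had corrected log2 fold changes of -0.28, 0.28, -0.21 and 0.78.

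In the adipocyte differentiation list, 1 of 12 tested genes rose and 5 fell, or 2 and 6 adjusted over the list alone (camera adjusted p = 0.239). PPARG, the master regulator of adipocyte formation, was at 6.64 ± 0.18 and 7.30 ± 0.36 FPKM and did not pass (adjusted p = 0.109). CEBPA was below the expression filter, at 0.044 ± 0.021 and 0.069 ± 0.044 FPKM. FASN, the fatty acid synthase, fell from 59.2 ± 0.81 to 44.0 ± 1.84 FPKM, the lipase gene PNPLA2 and CEBPD fell by 0.47 and 0.51, and KLF4 rose from 14.6 ± 1.02 to 22.8 ± 1.74 FPKM. Of 10 genes from the 12q13-15 region that is amplified in many liposarcomas, 4 rose and 2 fell in both adjustments (camera adjusted p = 0.437). CDK4 fell from 53.9 ± 1.75 to 44.3 ± 3.77 FPKM and OS9 fell by 0.41, while HMGA2 and FRS2 rose by 0.36 each. After GC and length correction adipocyte genes had 1 rise and 4 falls, with FASN at -0.13 and PNPLA2 at -0.17, and CEBPD (-0.17) no longer passed. PPARG was at 0.012. The 12q13-15 list then had 1 fall, of OS9, and CDK4 (-0.17), HMGA2 (0.14) and FRS2 (0.13) no longer passed. Extracellular matrix and mesenchymal genes had 5 rising and 9 falling of 24, or 7 and 9 adjusted over the list alone (camera adjusted p = 0.549). COL1A1, the main fibrillar collagen, fell from 121 ± 5.13 to 89.0 ± 5.49 FPKM, and COL5A1 and the protease gene MMP14 fell by 0.42 and 0.37. After correction 2 of this list rose and 5 fell, with COL1A1 at -0.20, COL5A1 at -0.19 and MMP14 at -0.15.

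Inflammatory genes of the NF-kB pathway had 7 rising and 4 falling of 19, or 7 and 5 adjusted over the list alone (camera adjusted p = 0.808). IL6, a cytokine gene at 54.0 ± 4.63 FPKM in NC, rose by 0.89 on the log2 scale (adjusted p = 0.00270), and IL1A and TNFAIP3 rose by 0.46 and 0.49. CCL2, a monocyte chemokine, fell from 57.2 ± 7.80 to 38.1 ± 2.69 FPKM. Unfolded protein and integrated stress genes had 6 rising and 9 falling of 22 in both adjustments (camera adjusted p = 0.666), where DDIT4, SHMT2 and PHGDH fell by 0.50, 0.47 and 0.45 and DNAJB9 rose by 0.43. Of 19 cholesterol synthesis genes, 7 rose and 9 fell, or 8 and 9 adjusted over the list alone (camera adjusted p = 0.991). CYP51A1 and MVD fell by 0.54 and 0.41, and STARD4 and MSMO1 rose by 0.51 and 0.46. Hypoxia and glycolysis genes had 4 rising and 5 falling of 24, or 6 and 7 adjusted over the list alone (camera adjusted p = 0.922). P4HA1, PDK1 and KDM3A rose by 0.34, 0.34 and 0.28, and CA9, a carbonic anhydrase, fell by 0.36. Of 13 heat shock genes, 3 rose and 6 fell, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.867), with HSPA1B, HSPA1A and HSPB1 falling by 0.65, 0.62 and 0.50 and HSPH1 rising by 0.24. HSPA1A and HSPA1B are near-identical copies, so the division of reads between them is uncertain. RNA polymerase I and ribosome biogenesis genes had 6 rising and 7 falling of 23 in both adjustments (camera adjusted p = 0.922), where RRS1, BOP1 and UBTF fell by 0.54, 0.49 and 0.38 and TAF1B rose by 0.38. After GC and length correction the rises and falls were 3 and 1 for NF-kB, 0 and 4 for stress, 3 and 2 for cholesterol, 1 and 2 for hypoxia, 0 and 2 for heat shock and 0 and 2 for ribosome biogenesis. None of the named hypoxia genes passed then, with P4HA1 at 0.17, PDK1 at 0.13, KDM3A at 0.12 and CA9 at -0.10. No call was left either for DDIT4 (-0.28), DNAJB9 (0.25), MVD (-0.13), MSMO1 (0.26), HSPA1A (-0.38), HSPH1 (0.040), RRS1 (-0.36) and TAF1B (0.19). Smaller than before, but past the threshold, were IL1A (0.27), SHMT2 (-0.29), PHGDH (-0.40), STARD4 (0.28), HSPA1B (-0.42), HSPB1 (-0.19), BOP1 (-0.18) and UBTF (-0.26), while CYP51A1 was at -0.69.

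Only 5 of 19 replication-dependent histone genes were tested. H2BC5 rose by 0.38 and none passed adjusted over the list alone (camera adjusted p = 0.666), and H1-2 was at 5.08 ± 0.21 and 5.52 ± 1.55 FPKM and H2AC6 at 1.62 ± 0.10 and 1.80 ± 0.22. Markers of other cell types were read in the same fit. Of the 4 leukocyte markers tested, LAPTM5 rose by 0.31 and CORO1A fell by 0.32 in both adjustments. PTPRC, the pan-leukocyte marker, was at most 0.007 FPKM in a TP53INP2_OE library. Of the 4 epithelial markers tested, the keratin genes KRT18 and KRT8 fell by 0.28 and 0.25, and the same 2 passed adjusted over the list alone. Among 8 endothelial markers 1 rose and 3 fell in both adjustments (camera adjusted p = 0.735). TEK rose by 0.28, while ERG, CDH5 and TIE1 fell by 0.29, 0.21 and 0.19, and TIE1 turned to 0.0485 after the GC and length correction. Of 5 fibroblast and preadipocyte markers, 4 fell, or 1 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.239). PDGFRB, TAGLN and S100A4 fell by 0.41, 0.32 and 0.27, and ENG fell by 0.21 but turned to 0.073 after the correction. With the correction LAPTM5 and PI16 rose by 0.35 and 0.69 and no other member of these 5 lists passed. The corrected log2 fold changes were 0.37 for H2BC5, -0.046 for CORO1A, -0.12 for KRT18, -0.10 for KRT8, 0.20 for TEK, -0.35 for ERG and -0.091 for CDH5. They were -0.23 for PDGFRB, -0.15 for TAGLN and -0.12 for S100A4, and 0.27 for H1-2 and -0.040 for H2AC6, which had not passed before. The list median, mean and test direction differed in sign for the mitophagy, NF-kB, heat shock and cholesterol lists, none of which passed.

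**Figure D4:**
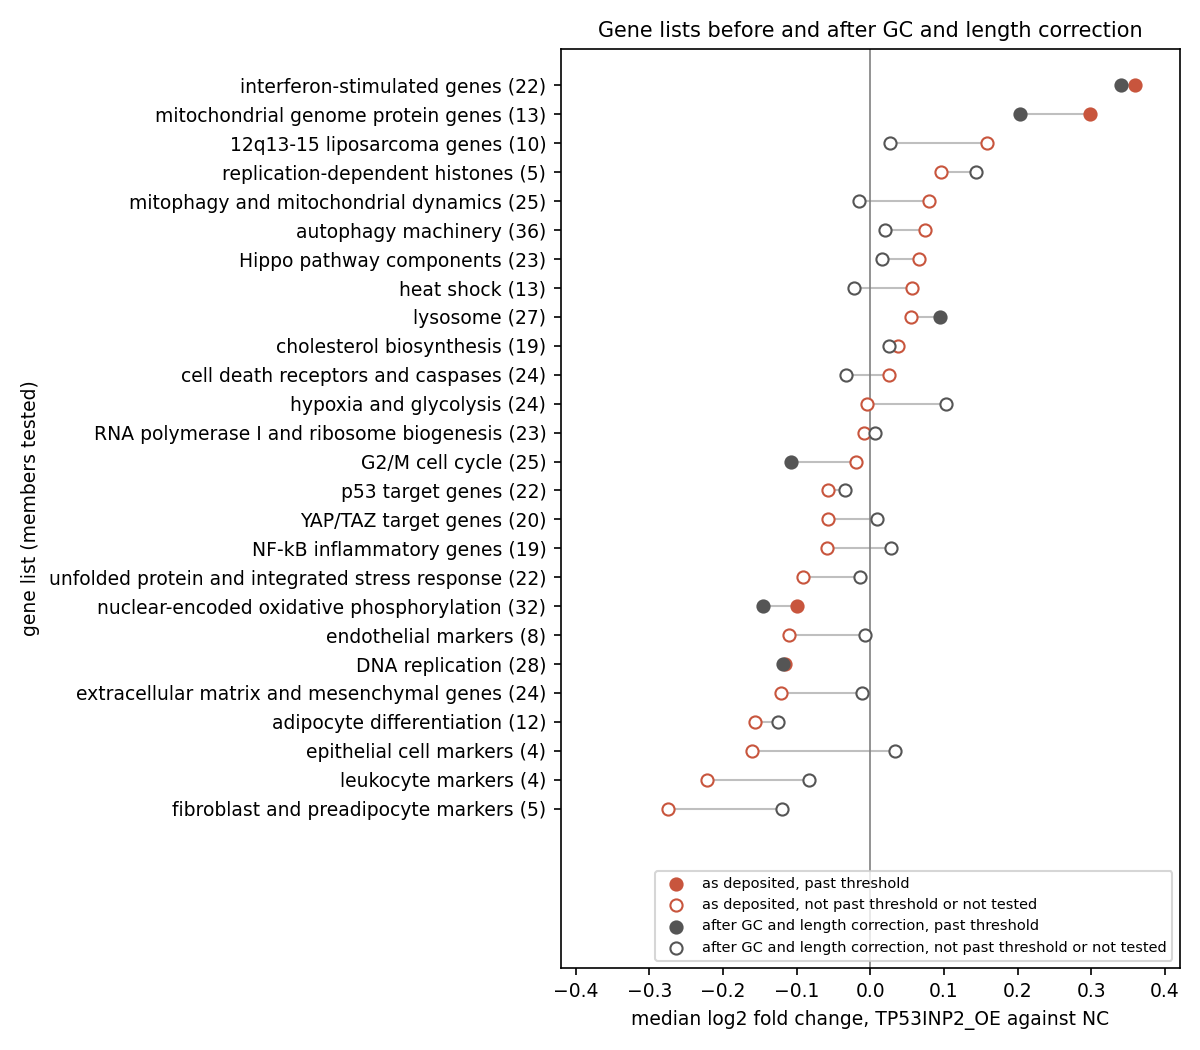
Median log2 fold change (TP53INP2_OE against NC) of the tested members of 26 gene lists, with the number of members tested in parentheses, as deposited and after GC and length correction; filled points are lists past the adjusted threshold, and lists with fewer than 5 tested members were not tested. The interferon-stimulated and mitochondrial genome lists lie highest at 0.359 and 0.298, and 4 lists are past the threshold before and 6 after the correction. With an estimated correlation no list passed before or after the correction.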

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

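Voom, the GC corrections and the fit to protein-coding genes were chosen after the results were seen. Every setting kept TP53INP2 higher and past the threshold, with log2 fold changes from 1.01 to 1.29 (1.01 to 1.26 over the fits that left out 1 library). The 5183 genes past the threshold became 3276 to 4779 when a library was left out (1460 to 2203 higher, 1816 to 2576 lower). They became 1573 with GC correction (585 higher, 988 lower), 1585 with GC and length correction (581 and 1004) and 67 with a minimum log2 fold of 1 (37 and 30), which keeps fewer genes by construction. The other settings gave 3648 to 6142. Of 112 named genes past the threshold, 69 kept their call and direction with GC correction, 68 with GC and length correction and 88 to 104 with a library left out. The direction turned for TIE1 (0.0577 with GC correction, 0.0485 with GC and length) and ENG (0.0717 and 0.0732), where the subtracted trend was larger than their falls. MT-CO2 went to 0 under quantile normalization, which gives genes of equal rank the same value in every library. The 4 lists past the threshold became 3 or 4 with a library left out, 2 among genes of at least 5 FPKM, 2 among protein-coding genes and 1 under quantile normalization. They became 10 by fry and 0 by camera with an estimated correlation, where 1 list had an unadjusted p below 0.05. For the nuclear-encoded oxidative phosphorylation list a larger correlation is not the reason, since its estimate of 0.00836 was below the preset 0.01. In that mode camera also takes its degrees of freedom from the 6 libraries and not from the genes. How much each part contributed to the lost calls was not tested. With the estimated correlation the interferon-stimulated list had an adjusted p of 0.434. By fry, a test that does not compare a list with other genes, the autophagy list had 0.0238. The YAP/TAZ and mitophagy lists stayed on the same side of the threshold in every setting. Replicate numbers did not pair the libraries (correlations of deviations 0.017, 0.012 and 0.011, and number 2 and 3 did not correlate best with their own number), and with a replicate block 4396 genes passed (1980 higher, 2416 lower) and the nuclear-encoded oxidative phosphorylation list had an adjusted p of 0.0527. Median-of-ratios factors were equal in all libraries (1.0071), so the deposited values were already on that scale. That setting could move nothing and is no test of the scaling. The planned count-based tests were not run, since the values are FPKM. With 16038062 to 17607612 assigned reads per library, genes resting on a few reads, such as RNA5SP219, have no usable fold.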

Other observations

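The gene groups of the first paragraphs, and the tests on copy number, leukocytes and the construct, were chosen after the results they address were seen. Ribosomal protein genes formed another group that moved. Of 79 cytosolic ribosomal protein genes, 45 fell and 1 rose (median log2 fold change -0.188, camera adjusted p = 1.77e-10; adjusted p = 0.434 with an estimated correlation), and after GC and length correction 42 fell and none rose (median -0.190). RPL36 fell from 103 ± 7.60 to 51.8 ± 8.96 FPKM and RPL37 from 45.2 ± 1.67 to 29.2 ± 4.19 (SD, n = 3 each). Of 77 mitochondrial ribosomal protein genes, 29 fell and 14 rose (camera adjusted p = 0.00843; adjusted p = 0.434 with an estimated correlation), and 20 fell and none rose after the correction. Many ribosomal protein genes have pseudogene copies, so their reads are partly uncertain. Genes with short coding parts tended the same way: across 11267 protein-coding genes, the corrected fold change and the coding length had a Spearman rho of 0.141, with genes as the units, which are not independent replicates. Among the 1134 genes with coding parts of at most 555 bases, 192 fell and 37 rose after the correction. TMSB10, an actin-binding peptide gene, fell from 1957 ± 104 to 1128 ± 169 FPKM. Among 20 collagen genes, 13 fell and 1 rose (camera adjusted p = 6.34e-05; adjusted p = 0.434 with an estimated correlation), and 6 fell and 2 rose after the correction.

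Of 28 genes of chemokines, interleukins and colony-stimulating factors, 11 rose and 3 fell, and the family did not pass (camera adjusted p = 0.0954). After the correction 5 rose and 2 fell (camera adjusted p = 0.0141; adjusted p = 0.358 with an estimated correlation). In this family CCL2 fell by 0.57 on the log2 scale, and CSF3, which encodes G-CSF, rose from 8.65 ± 1.24 to 15.1 ± 2.16 FPKM. Outside it, LTB fell by 1.62, and VEGFC, a lymphatic growth factor, rose from 5.81 ± 0.39 to 11.6 ± 0.46 FPKM. The collagen-binding integrin gene ITGA2 rose from 52.2 ± 6.48 to 108 ± 4.93 FPKM. Each of these genes passed with and without the correction. Of 17 integrin genes, 7 rose and 4 fell (camera adjusted p = 0.409), and 3 rose and 3 fell after the correction. ZC3HAV1, an antiviral zinc finger gene, rose from 33.9 ± 2.26 to 64.5 ± 2.62 FPKM. Both groups expressed genes typical of endothelial cells, with TIE1 at 57.8 ± 2.02 FPKM in NC and 50.6 ± 2.97 in TP53INP2_OE and CDH5 at 32.3 ± 2.46 and 27.8 ± 0.72, while VWF was at 0.70 ± 0.04 and 0.81 ± 0.01. The adipocyte genes FABP4, ADIPOQ and LEP were listed at 0 in all 6 libraries, and PDGFRA was at 0.075 ± 0.017 FPKM in NC. MDM2, amplified in many dedifferentiated liposarcomas, was at 3.26 ± 0.20 FPKM in NC.

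As to how many genes chance could give, the real grouping called 5183 genes and the highest of the other splits of the 6 libraries called 5. The 1 of the 10 splits that gave as many was the real grouping itself. With 10 splits the share cannot go under 0.1, so they are too few for a share under 0.05. After GC and length correction the values were 1585 and 2.

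Fold changes followed GC content. The GC slopes of the groups were separated by 0.154, more than the larger range within a group, 0.082. That gap is larger than variation between libraries unrelated to the groups was predicted to give. It cannot exclude such variation, since the 6 libraries have only 10 splits. Whole-chromosome copy number is argued against as the whole cause, because rho between fold change and GC content inside single chromosomes ran from -0.799 to -0.632 over 23 chromosomes, although chromosome 19 alone among them still passed after GC and length correction (median -0.061, camera adjusted p = 0.0231; adjusted p = 0.265 with an estimated correlation), so a smaller difference in its copy number stays open. A candidate explanation that stays open is a difference in library preparation or sequencing between the groups. The slope in 433 long non-coding RNA genes was -0.216 ± 0.018 (standard error over genes, which are not independent replicates) per 10 points of GC. It was close to the -0.255 of protein-coding genes. No label gives preparation batches, and a further difference between the 2 cell sources of the design text, or an effect of TP53INP2 itself, was not tested and stays open too.

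For the rise of interferon-stimulated genes, GC content or the deposited gene length as the whole cause is argued against by the corrected median of 0.34 against 0.359 before. Leukocytes mixed into the cultures are argued against by PTPRC at no more than 0.007 FPKM in any TP53INP2_OE library, although LAPTM5, 1 of the 4 leukocyte markers above the expression filter, rose with and without the correction. A response to the introduced construct or to transfection cannot be told apart from one to TP53INP2, because the construct in NC is not described in the labels, and a difference in cell source was not tested and stays open. IFNB1 stood at 2.326 FPKM in TP53INP2_OE and 2.133 in NC, which decides nothing. The list's call was lost with an estimated correlation before the correction (adjusted p = 0.434) and after it (0.0995).

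The opposite shift of mitochondrial genome and nuclear-encoded respiratory genes may not come from GC content or the deposited gene length alone. The corrected median of the nuclear genes was -0.146 with a standard error of 0.028. Transcript length was not fitted out, so a bias with it stays open. The members of a list are not independent replicates. Under scaling by total reads, the larger mitochondrial share would give a displacement of -0.01 on the log2 scale, against a median of -0.10. The deposited values were already on a median-of-ratios scale (factor 1.0071 in all libraries), which does not follow that share. This comparison is therefore no test of that explanation. Loss of short coding transcripts in general stays open. A share of 0.0248 of 10000 lists matched on coding length, GC content and expression had a median as low. The 2.5th percentile of these lists was -0.10, equal to the list's median after rounding, and the draws take genes as independent. Among the genes with the shortest coding parts, 192 fell and 37 rose after the correction. The matched genes had a median coding length of 654 bases against 628 for the list. A difference in library preparation was not tested for this pattern and stays open, as does TP53INP2 itself.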
